A study of Caenorhabditis elegans with 2 samples.

How the data were processed

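The study is a transcription factor ChIP-seq experiment from the ENCODE project on Caenorhabditis elegans. Late embryos, synchronised by egg bleaching and aged 2.5 hours per the labels, carried UNC-3 fused to a tag that includes enhanced green fluorescent protein, and chromatin sheared by sonication to fragments of 200 to 800 bp was precipitated with an antibody against GFP per the description, while the antibody field of the labels names unc-3. The event from which the 2.5 hours are counted is not stated here, so the age alone does not fix the stage. The labels give 1 group of 2 biological replicates, called replicate 1 and replicate 2 here. They name no treatment or time course, and the input or control library they point to was not used here, so no comparison between groups was made and no background from an unprecipitated sample stands beside the values.

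The values are peak lists that the authors deposited on the assembly ce11, per the labels. Each replicate has a ranked list and a shorter thresholded list, and both replicates together have 2 ranked and 2 thresholded lists, of which the one named conservative is the main list. In all lists the deposited signal value is taken as a measure of peak strength, and its definition and unit are not given in the sources used here. Signal values of the lists for both replicates were used to rank and describe peaks, to compare main peaks with and without a motif, and to describe ranked peaks beside main peaks. For main peaks their median was 81.5, against 43.7 in replicate 1 and 41.0 in replicate 2. Values for both replicates and for 1 replicate should thus not be set against each other. The deposited score is a scaled form of the irreproducible discovery rate (IDR), and the deposited ranked lists also give the IDR on a −log10 scale. The aligner, the peak caller and its settings, the read length and any list of excluded regions are not given in the sources used here. The lists hold no read counts, so the depth of each library is unknown, and the intervals below are exact Clopper-Pearson intervals at the 95% level over peaks, which cover counting error only.

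Chromosome lengths matched the WBcel235 assembly, and genes came from Ensembl release 115. The 5' ends are annotated ends, which in this organism are often trans-splice sites instead of transcription start sites. Coordinates are 1-based. Main peaks were compared with lower ranked peaks, meaning peaks of the ranked list for both replicates that overlapped none of the 4 thresholded lists. The lower ranked peaks include 148 that passed an IDR limit of 0.01, and 1 alternative left these out. Shares were compared with Fisher's exact test, two-sided. A promoter-proximal summit lay within 500 bp of a 5' end of a protein-coding transcript. Motifs were searched within 100 bp of the summit on both strands, with Benjamini-Hochberg adjustment over 9 motifs, of which 3 were rearranged controls. Centring used windows of 500 bp on each side and an exact binomial test against uniform placement. Differences of medians and correlations over peaks used two-sided permutation tests with 100000 resamples, and peaks are not independent replicates. Peaks on the mitochondrial chromosome were left out of tests of location, motifs and genes.

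Gene lists, 27 in all, were fixed before the data were examined. They covered cholinergic and other neuronal functions, Hox genes, ciliary genes, markers of muscle, pharynx, intestine, epidermis, germ line and glia, families such as ribosomal protein, histone, collagen and nuclear receptor genes, and a mixed list of housekeeping genes, named general transcription and translation factors in the tables although most of its members are neither. A gene counted as bound when a main summit lay between 2000 bp upstream of its 5' end and its 3' end. The word means only this, and not that UNC-3 itself was shown to bind there. The number of bound members was compared with random lists drawn within 10 strata of window length from all 19973 protein-coding genes, in a two-sided permutation test with 100000 resamples and Benjamini-Hochberg adjustment over lists, with a threshold of 0.05. The smallest p this test can give is 2e-05. For 5 list entries no protein-coding gene of that symbol was found, directly or through synonyms. Named genes follow a rule fixed before the data were examined: the unc-3 locus, the 20 main peaks of highest signal, and up to 4 bound members of highest signal from each neuronal list and each list past the threshold. Peaks named for holding the COE motif were chosen after their values were seen.

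The list test was tested on simulated data over 19973 genes: it called 3.67% of 300 unchanged lists of 80 genes and 100% of 300 lists with 16 planted bound members. These calls used an unadjusted p under 0.05, and the simulated lists resemble only that of ribosomal protein genes. Shorter lists and weaker excesses were not simulated, nor was the adjustment over lists. Bound genes were drawn independently of each other, whereas in the data neighbouring genes can share a peak. The share of unchanged lists called may thus differ in the real data. The motif search found 60 of 60 planted exact sites, which checks only that the search works. Alternatives fixed before the data were examined covered the other series-level list, the upper part of the list by signal, each replicate alone, overlap rules, distances, windows, the motif pattern, backgrounds and gene windows. Alternatives and tests chosen after the data were examined were the removal of peaks in multi-copy sequence, of narrow peaks, of peaks within 500 bp of a tRNA gene and of ranked peaks past the IDR limit, a gene background limited to promoters with a ranked peak, lower ranked peaks matched on GC for the motifs other than COE, the share of coding exons over all summits, the comparison of all 6 chromosomes, the comparison with 6 classes of RNA genes, and a search over all 8-base words present in at least 20 peaks. Multi-copy sequence means that over 50% of the 36-base words in a peak occur more than once in the genome. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.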

Results

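Chromatin precipitated through a GFP-tagged form of UNC-3 was mapped in whole late embryos of Caenorhabditis elegans. Without a control library, a peak alone does not show that UNC-3 was bound there. UNC-3 is the worm member of the COE (Collier/Olf/EBF) family of transcription factors and is known as a terminal selector of cholinergic motor neurons, a factor that switches on the genes of a mature neuron type. The data are lists of peaks from 2 biological replicates, and the depth of each library is unknown. The question the design poses is where in the genome the precipitated chromatin gave peaks, and whether both replicates gave them in the same places.

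The main list held 631 peaks, with a median width of 264 bp and a median signal of 81.5. Replicate 1 alone gave 353 peaks and replicate 2 alone 384, and the ranked lists from which they came held 33914 and 34079. Of the replicate 1 peaks, 223 (63.2%, 95% interval 57.9 to 68.2) overlapped a peak of replicate 2 by at least 1 bp, where 2.45 were expected by chance from the union of both ranked lists (odds ratio 583, Fisher's exact test with a p too small to be represented). Of the replicate 2 peaks, 224 (58.3%, 53.2 to 63.3) overlapped a peak of replicate 1. The 384 peaks include 17 mitochondrial ones, for which replicate 1 had no peak to overlap. Over the 621 main peaks with a ranked peak in both replicates, the log10 signal of one replicate correlated with that of the other (Pearson r = 0.771, Spearman rho = 0.631, permutation p = 1e-05 for both, the smallest the test can give), and r was 0.759 without the 2 peaks farthest from the median. The correlation is across peaks that had been selected for reproducibility, and 212 of the main peaks overlapped no thresholded peak of either replicate alone. Signal unrelated to UNC-3 that recurs in both replicates could also overlap and correlate. Within 500 bp of a tRNA gene lay 30.6% of replicate 1 peaks and 28.9% of nuclear replicate 2 peaks. Neither the overlap nor the correlation was computed without such peaks.

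**Figure D1:**
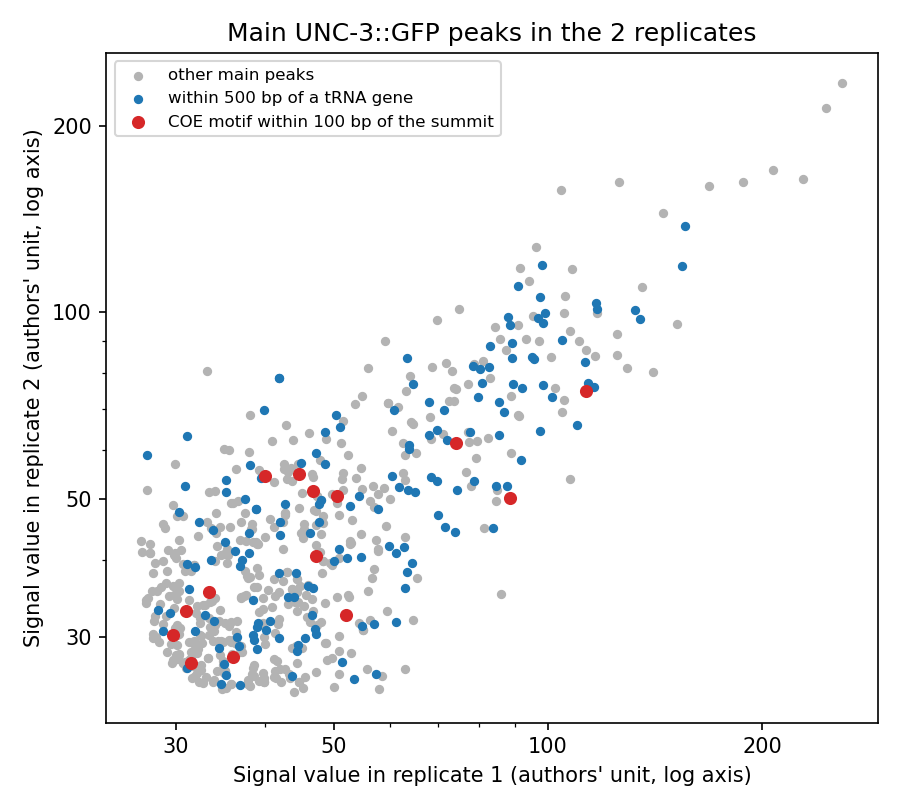
Signal value of each main peak in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), in the authors' unit. Each point is 1 of 621 main peaks with a ranked peak in both replicates, red for peaks with the COE motif, blue for peaks within 500 bp of a tRNA gene and grey for others. Pearson r of the log10 values was 0.771.

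The binding sequence of the COE family, TCCCNNGGGA, was more frequent at main peaks than at lower ranked peaks, and sat close to the summits. It occurred within 100 bp of 15 of 631 main summits (2.38%, 95% interval 1.34 to 3.89) and 93 of 29504 lower ranked summits (0.315%), an odds ratio of 7.70 (Fisher's exact test, adjusted p = 2.41e-08). The odds ratio was 6.36 against lower ranked peaks matched on GC, 4.83 with windows of 250 bp and 15.3 against windows 1000 bp away from main summits. The 3 rearranged controls were found at 1, 3 and 0 main peaks, with adjusted p-values of 1, 0.196 and 1. Of 16 motifs within 500 bp of main summits, 15 (93.8%, 69.8 to 99.8) lay within 100 bp, against 19.4% for uniform placement (exact binomial p = 2.62e-10). The exact motif was thus absent from 616 main peaks. The relaxed pattern YCCCNNGGGR was at 21 main peaks (3.33% against 0.644% of lower ranked peaks, odds ratio 5.31, Fisher's exact test, adjusted p = 1.98e-08). Peaks with the exact motif did not differ detectably in signal from those without it (median 88.0 against 81.5, difference 6.51, permutation p = 0.499). The difference was 0.506 without replicate 1, -5.90 without replicate 2 and -11.9 in the upper part of the list by signal.

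The peaks with the motif included the cholinergic gene locus. A peak on chromosome IV from 3621842 to 3622105 lay in an intron shared by cha-1 and unc-17, which encode choline acetyltransferase and the vesicular acetylcholine transporter, with the site TCCCAGGGGA at 3621926 to 3621935. Its signal was 89.4 in the main list, 47.3 in replicate 1 and 40.6 in replicate 2, and it was in the thresholded list of replicate 1 but not in that of replicate 2. The motif peak of highest signal, 190 in the main list and 113 and 74.8 in the replicates, lay intergenic on chromosome III from 665233 to 665496, 99 bp upstream of a 5' end of C09F5.3. Others lay in introns of egl-27 (signal 145), let-526 (100.3), plr-1 (72.4), zfh-2 (70.7) and lin-59 (56.9). A peak in an intron of tns-1 had a higher signal than that of let-526. Further peaks lay 1237 bp upstream of dmsr-7 (143), and 236 bp upstream of acy-1 (88.0), the gene of an adenylyl cyclase. The peaks at egl-27, tns-1, plr-1 and dmsr-7 were in the thresholded lists of both replicates. Those at let-526 and acy-1 were in that of replicate 1 only. Those at zfh-2 and lin-59 were in neither, and the zfh-2 peak had no ranked peak in replicate 1. These genes were named after their values were seen.

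The unc-3 gene itself (WBGene00006743, chromosome X, 14773538 to 14783568) held 1 main peak. It covered 14776392 to 14776655, with its summit in an intron 2986 bp downstream of the nearest 5' end. Its signal was 80.9, rank 323 of 631, with 44.1 in replicate 1 and 34.1 in replicate 2, and it was in neither replicate's own thresholded list. It held no TCCCNNGGGA, and a site of the relaxed pattern YCCCNNGGGR, TCCCGAGGGG, lay 79.5 bp from the summit. The labels name unc-3 as the target of the tag's insertion and yet place the tagged allele on chromosome II, while the annotated gene is on X. Whether the tag sits at this locus is thus not settled by the sources used here, nor is what a peak at it means.

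**Figure D2:**
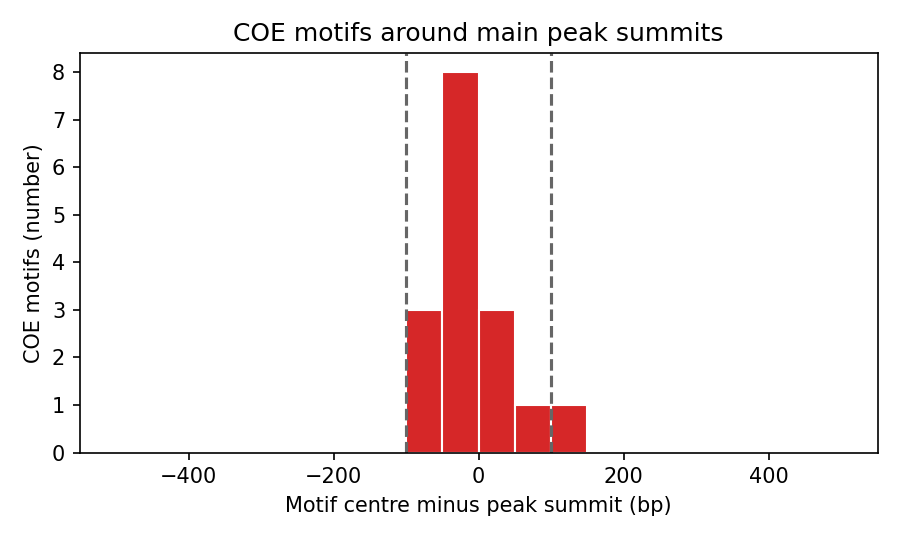
Number of COE motifs (vertical) by the distance of the motif centre from the summit in bp (horizontal, bins of 50 bp) in windows of 500 bp on each side of main summits. Dashed lines mark 100 bp on each side, within which 15 of 16 motifs lay.

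Of the 4 other sequence patterns, compared by Fisher's exact test, GAGAGA occurred at more main peaks than lower ranked peaks (29.2% against 14.3%, odds ratio 2.46, adjusted p = 2.39e-20). The GATA factor sequence TGATAA was less frequent at main peaks (7.61% against 14.3%, odds ratio 0.494, Fisher's exact test, adjusted p = 9.78e-07), as was the homeodomain sequence TAATTA (4.12% against 6.93%, adjusted p = 0.00739). The E-box CAGCTG was found at 5.07% and 4.65% (Fisher's exact test, adjusted p = 0.730). Main summits lay in sequence richer in GC, with a median of 45.8% against 39.3% within 100 bp. These patterns were therefore also compared with lower ranked peaks matched on GC, a choice made after the data were examined. GAGAGA stayed more frequent (18.2% of matched peaks, odds ratio 1.85, Fisher's exact test, adjusted p = 1.83e-09). TGATAA and TAATTA no longer passed (odds ratio 0.7001 and 0.930, Fisher's exact test, adjusted p = 0.0515 and 0.943). Their shares among matched peaks were 10.5% (95% interval 9.78 to 11.3) and 4.42% (3.92 to 4.96), closer to the 7.61% (5.66 to 9.96) and 4.12% (2.71 to 5.98) of main peaks.

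Main peaks lay near the annotated beginnings of genes and were nearly absent from coding sequence. Of 631 summits, 268 (42.5%, 95% interval 38.6 to 46.4) were within 500 bp of a protein-coding 5' end, compared with 25.6% of lower ranked summits (odds ratio 2.14, Fisher's exact test, p = 1.26e-19) and 23.004% of random genome positions. Of the rest, 201 were intergenic, 151 were in introns, 6 in coding exons and 5 in untranslated regions. These groups exclude each other, so the coding exon number covers only summits farther than 500 bp from a 5' end. Over all summits, whatever their distance, coding exons held 11 of 631 main summits (1.74%, 0.873 to 3.098) and 25.5% of lower ranked summits (Fisher's exact test, p = 2.52e-62).

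Ribosomal protein genes carried main peaks far more often than genes of similar length. Of 81 such genes, 18 had a main peak, where 2.12 were expected (ratio 8.48, permutation test, adjusted p = 5.4e-04, raw p at the test's smallest value of 2e-05). Without replicate 1 the number was 11 (ratio 8.59) and without replicate 2 it was 8 (ratio 6.05), and among genes with any ranked peak in the window the ratio was 4.94. Counting each peak only for its nearest 5' end gave 12 (ratio 6.27), as some summits in these windows lay nearer another gene. The members of highest signal were rpl-3 (200.4 in the main list, 93.9 and 112.3 in the replicates), rpl-15 (158), rpl-35 (145) and rpl-20 (136), each with an intergenic summit within 500 bp of a 5' end. A mixed list of widely expressed housekeeping genes, which spans RNA polymerase, translation factors, tubulins, chaperones, glycolysis, ubiquitin and proteasome genes, had 5 of 25 members bound, where 0.826 were expected (ratio 6.06, permutation test, adjusted p = 0.0321): tba-1, an alpha tubulin (signal 111.5), hsp-1, a heat shock protein 70 (86.4), eif-3.B, a translation initiation factor subunit (85.4), eef-1A.1, a translation elongation factor (78.4), and cyc-1, a cytochrome of the respiratory chain, which was named after its value was seen. With replicate 1's or replicate 2's list alone this second list did not pass (permutation test, adjusted p = 0.844 and 1), nor in 4 other alternatives.

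No neuronal list passed the threshold. Most of these lists are short, and how often the test would find a real excess in them was not simulated. Whole embryos were used, so sites bound in only a few cells may be missed. Cholinergic transmission had 2 of 7 members bound, where 0.448 were expected (permutation p = 0.139, adjusted p = 1): these were cha-1 and unc-17, which share 1 peak. Without replicate 1 the list had 0 of 7 bound. The same pair made up the 2 of 23 bound motor neuron effector genes (1.29 expected), and unc-3 was the 1 of 18 bound motor neuron transcription factors (0.863 expected). Axon guidance and synapse formation had 5 of 43 bound (2.87 expected), led by the ephrin receptor gene vab-1 (signal 96.0), the cell adhesion gene sax-7 (73.4), unc-115 (66.6) and the semaphorin gene mab-20 (62.5). Pan-neuronal genes had 3 of 30 (1.75 expected), the kinesin gene unc-104 (122), unc-33 (82.2) and the ankyrin gene unc-44 (72.4). Monoamine neuron identity had 2 of 18 (0.992 expected), the vesicular monoamine transporter gene cat-1 (169) and the receptor gene ser-2 (70.1). Neuropeptide genes had 3 of 142 (4.03 expected), nlp-76 (214), flp-23 (96.8) and nlp-81 (57.96). Acetylcholine receptor subunits had 1 of 32 (1.72 expected), acr-18 (102), and ion channels 1 of 42 (2.76 expected), the potassium channel gene unc-58 (122). Chemosensory neuron genes had 1 of 24 (1.05 expected), the channel gene osm-9 (89.3), and ciliary genes 2 of 31 (1.72 expected), che-13 (122) and daf-19 (56.6). GABA and glutamate neuron lists had 0 of 12 and 0 of 21 members bound. With 0.680 and 1.17 expected, even a count of 0 could not pass. The peaks counted for acr-18, cat-1, ser-2, unc-33, unc-115, unc-58, nlp-76, flp-23 and osm-9 lay within 500 bp of a tRNA gene, and the nlp-76 summit was in an intron of nhr-17. Without peaks at tRNA genes, an alternative chosen after the data were examined, the monoamine, acetylcholine receptor, ion channel and chemosensory lists had 0 members bound. Under it neuropeptide genes had 1, pan-neuronal genes 2, and axon guidance and synapse formation 4. The list of each replicate alone gave 2 bound axon guidance and synapse formation genes and 0 bound motor neuron transcription factors. Without replicate 1, pan-neuronal genes had 1 bound and neuropeptide genes 2, and without replicate 2 they had 3 and 1.

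Among the remaining lists, none of which passed, Hox genes had 1 of 6 bound (ceh-13, signal 61.0, 0.299 expected). Body wall muscle had 1 of 31, pharynx 1 of 18, intestine 1 of 34, epidermis 1 of 36, glia 1 of 14 and the germ line 0 of 32. Histone genes had 4 of 72, several of which were counted from the same peak. Homeobox genes of the ceh class had 2 of 63, nuclear receptors 6 of 269, bHLH genes 0 of 25 and collagens 6 of 156. All had an adjusted p of 1. Without peaks at tRNA genes collagens had 2 bound, nuclear receptors 3, ceh homeobox genes 1, and pharynx and epidermis 0.

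**Figure D3:**
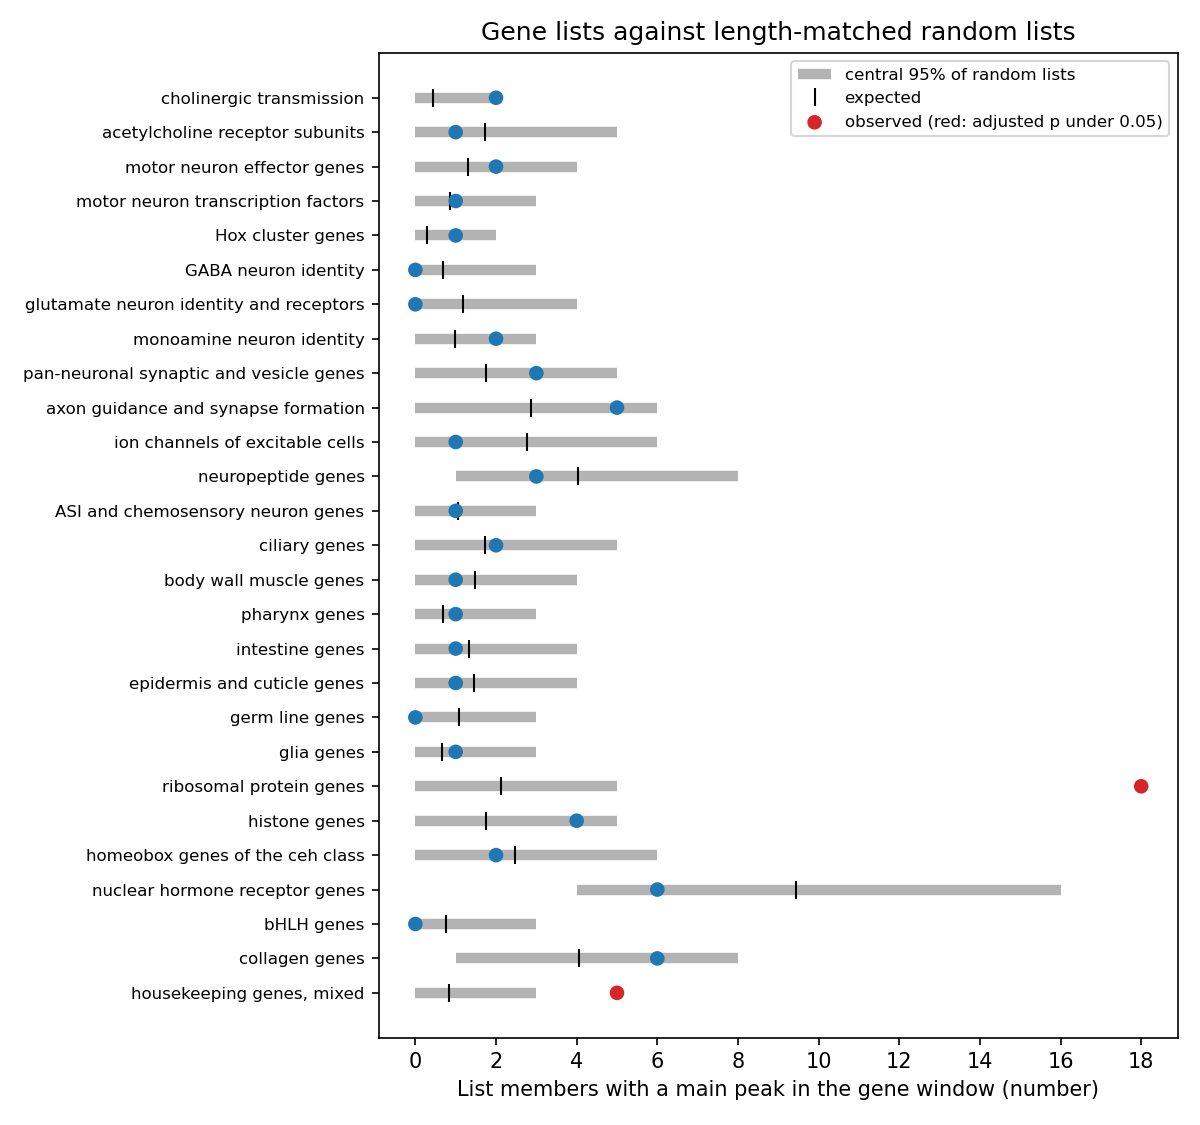
Number of members of each gene list with a main peak in the gene window (horizontal). Points are observed numbers, red where the adjusted p was under 0.05, black ticks are expected numbers and grey bars span the central 95% of random lists matched on window length; ribosomal protein genes stand at 18 against 2.12 expected.

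The X chromosome carried 134 of 631 main peaks (21.2%, 95% interval 18.1 to 24.6), compared with 16.2% of lower ranked peaks (odds ratio 1.39, Fisher's exact test, p = 0.00108). X was the chromosome chosen for testing before the data were examined. When all 6 chromosomes were compared afterwards, V held fewer main peaks (13.5% against 18.6%, odds ratio 0.680, Fisher's exact test, adjusted p = 0.00325, the same as for X), and I, II, III and IV did not pass. Transfer RNA genes, of which 276 of 612 lie on X, were within 500 bp of 160 main summits, 78 of them on X. Without the main peaks at tRNA genes, an alternative chosen after the data were examined, the direction turned: X held 56 of 471 main peaks (11.9%, odds ratio 0.696, Fisher's exact test, p = 0.00965). Lower ranked peaks were kept whole in this comparison.

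Of the 20 main peaks of highest signal, 12 had their summit within 500 bp of a tRNA, snoRNA or snRNA gene, as did 218 of all 631 main peaks (34.5%). None of the 20 held the COE motif (95% upper limit 16.8%), too few to differ from the 2.38% of all main peaks. The highest lay on chromosome V from 12303510 to 12303740 in an intron of frm-7 (signal 500.8, 259 in replicate 1 and 234 in replicate 2). It was followed by an intergenic peak on III from 8043873 to 8044052, 523 bp upstream of K12H4.5 (467), one on II from 11960700 to 11960926 with W03C9.1 nearest (394), and one in an intron of pxn-1, which encodes a peroxidasin (373). The other 16 had signals between 222.2 and 354. Their nearest genes or host genes included sre-23, cutl-18, str-56, him-4, col-181, lev-9, atx-2, spd-5, idhg-1, mpk-2 and snx-17. The 12 peaks at tRNA, snoRNA or snRNA genes are not marked among the protein-coding genes named here. A named gene is thus a neighbour or host of its peak and need not be what the peak belongs to. Of the 20 peaks, 5 lay in multi-copy sequence; their nearest genes were Y54F10AM.8, Y53G8AR.1, col-181 and snx-17.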

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

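The test of multi-copy sequence on the peaks below was chosen after its result was seen.

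Among the ranked peaks for both replicates, 148 passed the IDR limit of 0.01 that main peaks reach and appeared in none of the thresholded lists. They were flagged as signal that the comparisons did not count as main peaks, although they were among the 29504 lower ranked peaks. Their signal reached 3288 (median 155), against a highest main signal of 500.8. Of these 148 peaks, 135 (91.2%, 95% interval 85.4 to 95.2) lay in multi-copy sequence, compared with 59 of 631 main peaks (9.35%), and 0 of 148 held the COE motif. A candidate explanation is that the lists were filtered against repeated regions, where reads from several copies pile up; whether such a filter was applied is not given in the sources used here. No biological explanation was tested.

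Mitochondrial peaks made up 17 of the 384 thresholded peaks of replicate 2 and 0 of the 353 of replicate 1, which flagged them as signal outside the nuclear comparisons; the 18 ranked ones covered 29.9% of the mitochondrial genome. Fisher's exact test on these counts gave p = 1.59e-05, but it sets 1 library against 1 other over neighbouring peaks and covers counting error only. The 2 deposited lists differ in these peaks, but 1 library of each cannot tell why, or whether the difference would recur.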

How the results depend on the processing

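The removals of peaks, the backgrounds limited to promoters or to peaks below the IDR limit, and the GC-matched background for motifs other than COE were chosen after the data were examined. The promoter share, the COE motif share, the COE centring, the replicate overlap and the signal correlation kept their direction and their side of the threshold under all alternatives run for them, including each replicate alone where that was run, though the COE odds ratio ranged from 4.83 to 15.3. The ratio for ribosomal protein genes stayed past the threshold throughout and ranged from 4.94 to 12.1. The number of peaks was 353 to 384 without one replicate. The X odds ratio turned to 0.696 without main peaks at tRNA genes, and stayed above 1 with p under 0.05 in the other alternatives. The signal difference between peaks with and without the COE motif was -11.9 in the upper part of the list and -5.90 to 0.506 without one replicate, never past the threshold, and the cause was not tested. The number of lists past the threshold fell from 2 to 1 in the upper part of the list, with 1 to 1 without one replicate, with the nearest 5' end only, and with genes limited to those with a ranked peak in the window or within 500 bp of a 5' end; each time the mixed list of housekeeping genes was lost. Its ratio of observed to expected, 6.06 in the main list, was 7.06 in the upper part and 4.25 to 4.51 in the others, so the ratio stayed far above 1 while the threshold was missed; the cause was not tested. Against GC-matched peaks TGATAA and TAATTA kept odds ratios below 1 (0.7001 and 0.930) without passing, and that of CAGCTG fell from 1.10 to 0.824, with neither past the threshold. For 57 list values the ratio fell on the other side of 1 with neither value past the threshold; these were not counted as turned. No paired analysis was possible because there is 1 group. Depth is unknown, so its effect on the number of peaks could not be computed.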

Other observations

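All tests in this part were chosen after the peak lists had been examined, and those of tRNA genes and of the COE motif on X were written or restated after their own results were seen.

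Genes transcribed into short structured RNAs were the most enriched neighbours of main peaks among the 6 RNA gene classes compared. A tRNA gene lay within 500 bp of 160 of 631 main summits (25.4%, 95% interval 22.005 to 28.9) and 0.871% of lower ranked summits (odds ratio 38.7, Fisher's exact test, adjusted p = 1.37e-160), and 133 of these summits lay inside the tRNA gene. Both replicates showed it, with 30.6% of replicate 1 peaks and 28.9% of replicate 2 peaks. Transfer RNA genes often give signal when unrelated proteins are precipitated, and without the control library it stays open whether UNC-3 itself binds at these peaks. Small nucleolar RNA genes, which guide RNA modification, were near 50 main summits (7.92% against 0.566%, Fisher's exact test, adjusted p = 9.22e-37), and small nuclear RNA genes, of which several act in splicing, near 9 (1.43% against 0.153%, adjusted p = 3.36e-06). Ribosomal RNA, microRNA and lincRNA genes did not pass (Fisher's exact test, adjusted p = 1, 0.895 and 0.364).

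Main peaks at tRNA genes had a median signal of 100.8 against 77.3 for the others, and 6.88% of them lay in multi-copy sequence. Of 32857 words of 8 bases, the lowest p belonged to GGGTTCGA, found at 11.1% of main and 0.708% of lower ranked summits (Fisher's exact test, adjusted p = 3.96e-50); it resembles the B box of tRNA genes, an internal promoter element. Of the 15 peaks with the COE motif, 1 was near a tRNA gene, too few to tell whether the motif is less frequent there.

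The excess of main peaks on X was examined under 4 explanations, of which tRNA genes were taken up last, after the RNA gene comparison. The word GCGCAGGG, the core of dosage compensation recruitment sites, was at 8 of 134 main X peaks (5.97%) and 0.313% of lower ranked X peaks (odds ratio 20.2, Fisher's exact test, p = 8.46e-08), and also more frequent at main peaks on autosomes (odds ratio 7.498). Without main peaks that hold it the X odds ratio was 1.32 (Fisher's exact test, p = 0.00831). Without main peaks in multi-copy sequence the X odds ratio was 1.40 (Fisher's exact test, p = 0.00165). Lower ranked peaks were kept whole in both comparisons, and neither explanation is thus the whole cause. Without peaks at tRNA genes in either set the X odds ratio was 0.707 (Fisher's exact test, p = 0.0157). It was lower than in each of 10000 random removals of as many main peaks. Those removals add no support, since 78 of the 160 main peaks at tRNA genes were already known to lie on X. The condition first written asked for a p above the threshold, which this deficit misses, and was restated as an end of the excess. It may be that the excess reflects the many tRNA genes on X, and the deficit that remains was not examined. Of the 15 peaks with the COE motif, 1 (6.67%, 0.169 to 31.9) was on X, too few to tell whether binding at the motif adds to or lowers the share.

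Main peaks at ribosomal protein genes, 19 in number, were also examined under 4 explanations. In multi-copy sequence lay 0% of them (upper limit 17.6), without peaks at tRNA, snoRNA and snRNA genes the ratio of observed to expected was 9.51, and among genes with any ranked peak within 500 bp of a 5' end it was 4.96 (both permutation p = 2e-05, the smallest possible), which argues against repeats, short RNA neighbours and an equal chance of a main peak at every promoter with a ranked peak as the whole cause. How accessible these promoters are was not measured and stays open. The COE motif was at 0% of them against 2.45% of the other main peaks, too few to decide. Signal that any tagged protein or control would give at highly transcribed genes stays open, since no control library was used.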
